A study of Homo sapiens with 50 samples.

How the data were processed

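The log2 values analysed were the authors' normalized values as deposited. According to the submitters' processing notes they had been made with lumi, whose version is not given in the sources used here. The base of the logarithm, the normalization options and the rule of the probe filter are not given there either, and the values were read as log2 from their range. Per the labels, RNA was extracted with QIAGEN kits and amplified to biotinylated cRNA with the Illumina TotalPrep kit. The deposited table held 5843 of the array's 47323 probes without missing values. The design, fixed before the data were examined, had assumed a normalization of scanner intensities (neqc) with a filter on detection p. The columns of both scanner tables carry numbers that match no sample label, so their 300 value columns (200 and 100) were not used, and neither were the detection p values.

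Of the probes 198 had no symbol and 12 belonged to XIST or Y-linked genes, and both kinds were left out, which left 5633 probes. Each of 4717 genes was represented by its probe with the highest mean, 752 genes having more than 1 probe. Accessions of 4658 probes were matched to current symbols, and of 15 symbols that a spreadsheet had turned into dates 12 were restored, SEPTIN5 among them. Symbols are those of the array, with current ones for IGJ (JCHAIN), SDPR (CAVIN2), IL8 (CXCL8), HIST1H2AC (H2AC6), HIST1H3H (H3C10), NUPL1 (NUP58) and TADA1L (TADA1). Probes of IGLL1 and IGLL3 resemble immunoglobulin lambda constant genes, and what they bind was not settled.

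Within each cell type a linear model of the isolation methods was fitted with limma (lmFit and eBayes) to all 4717 genes, two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes of its comparison. The number of arrays limits the precision of these tests. The main setting took no account of the donor, and the donor as a block was an alternative. Differences of a method effect between cell types were tested with a moderated F statistic in a fit of all cell types. Of 35 gene lists written before the data were examined (19 of pathways, 16 of cell type markers), those with at least 3 measured members were tested with camera (preset correlation 0.01), camera with an estimated correlation and fry, as a family of 330 tests. No gene of the list of respiratory chain subunits was measured, and too few of that of basophils and eosinophils (2), so these lists were not tested. The single FACS monocyte array was compared with the means of the other monocyte groups, with 10000 random gene lists as a reference. Alternatives were the donor as a fixed or random block, all cell types or only the 2 compared groups in a fit, every probe tested on its own, array weights, eBayes with trend and robust, a minimum change, other scalings of the deposited values, a filter on low means and leaving out each array in turn. Other groupings of the same arrays were counted as a check on chance. R 4.3.3, limma 3.58.1 and version 1.17.8 of data.table were used.

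Genes named were, by a rule set before the data were examined, the 8 largest changes in each direction among genes that passed, up to 4 members of a described list that passed and up to 2 that did not, fixed lead markers and response genes, and the 8 genes of largest F. Symbols of uncharacterised transcripts were excluded. Killer cell receptor (KIR) and HLA genes were left out of the naming later, because their gene content varies between people. Some genes that the rule names are not reported here. Of the lead genes PF4, FCGR3B, FOS, JUN, DUSP1, HSPA1B and NFKBIA were not in the deposited table.

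Replicate numbers in the titles name donors. After removal of group means, arrays of the same donor in different methods correlated with a median r across genes of 0.34 in CD4 cells, 0.31 in CD8 cells, 0.21 in B cells and 0.35 in monocytes, against -0.09, -0.05, -0.04 and -0.08 for different donors. Replicates of a group correlated between 0.919 and 0.968 across genes, and 0 pairs were identical.

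The steps were first run on simulated data with the group sizes and spreads of the arrays. Without a donor block a change of 0.5 log2 was recovered for 0% to 30% of genes over the 10 comparisons and 1 log2 for 42% to 82%. For 2 log2 this was 88% to 100% and for 4 log2 98% to 100%, and at most 8.70% of the calls were false. With the donor as a block, changes of 1 log2 were recovered for only 10% of genes in B FACS over positive selection. In B FACS over negative selection the figure was 4%. In each of these only 2 donors had both kinds of arrays. The share of false calls of the F tests was 14.9% and 14.3%, because cell types differ in spread. A simulated share of 10% monocyte RNA was estimated as 10.1% and one of 30% as 32.3%. This simulation used the mixing formula that the estimate inverts, on all 27 genes of the list, so it checks only the calculation under added noise. Shares in the real samples also assume that the deposited values are log2 of a linear signal, which the sources do not state.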

Results

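Gene expression was measured on Illumina bead arrays in 4 types of primary human leukocytes from 5 donors: CD4+ T cells, CD8+ T cells, B cells and monocytes. Each cell type had been isolated by 3 methods. In fluorescence-activated cell sorting (FACS) labelled cells are sorted individually in a flow cytometer. Positive selection retains antibody-labelled target cells, and negative selection removes labelled cells of the other types and leaves the target cells untouched. The 50 arrays comprised 5 FACS, 5 positive and 5 negative samples of CD4 cells, 5, 5 and 4 of CD8 cells, 3, 4 and 4 of B cells, and 1, 5 and 4 of monocytes. Replicate numbers are donor numbers, so arrays of the same number share a donor. From the deposited log2 values, which the authors had filtered by probe, 4717 genes were taken. The rule of that filter is not known, so shares of genes and list tests hold for these genes only. Mean array medians lay between 5.85 in FACS B cells and 6.12 in positively selected CD4 cells, and the number of arrays limits the precision of every value. All changes below are log2 differences with the method named before the other as the numerator, and error terms are SD for group means and SE for changes.

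**Figure D1:**
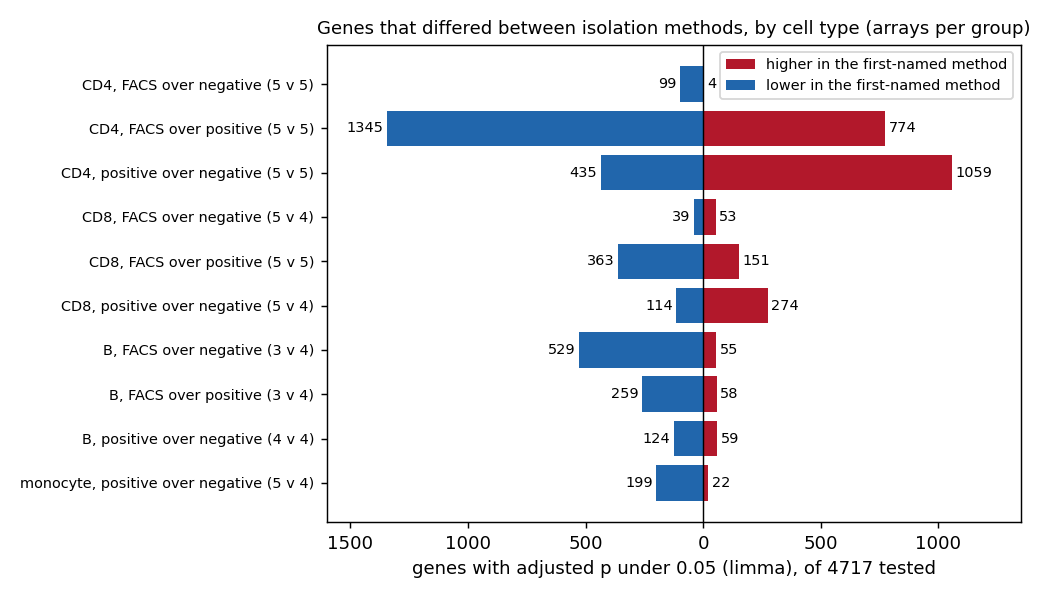
Number of genes with an adjusted p under 0.05 in each of the 10 comparisons within a cell type (horizontal axis, genes), higher in the method named before "over" to the right and lower to the left, with the number of arrays per group in brackets. The counts run from 92 genes in CD8 cells, FACS over negative selection, to 2119 in CD4 cells, FACS over positive selection, where the larger side turns to higher genes (1539 higher and 947 lower) with quantile normalization.

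The comparison of FACS with negative selection in CD4 T cells asked what sorting changed relative to cells that had not been labelled. Platelet and megakaryocyte transcripts were lower after FACS. So were replication-type histone genes, whose transcripts platelets also carry, IGJ and the IGLL1 probe, and genes of memory and cytotoxic T cells. TUBB1, the platelet beta-tubulin, averaged 5.63 ± 0.36 (n = 5) after FACS and 8.42 ± 1.07 (n = 5) after negative selection, a change of -2.78 (SE 0.38). GNG11, SDPR (now CAVIN2), RGS18 and PPBP, the precursor of a chemokine held in platelet granules, changed by -2.97, -2.85, -3.03 and -2.55. Of 20 measured platelet genes 10 fell (16 adjusted over the list alone), with a median change of -0.82 (camera adjusted p = 3.60e-19, and adjusted p = 0.114 with an estimated correlation). Replication-type histone genes moved the same way: 5 of 9 fell (9 adjusted over the list alone), among them HIST1H2AC at -2.03 and HIST1H2BD at -1.23, with a median of -0.76 (camera adjusted p = 6.69e-11, and adjusted p = 0.114 with an estimated correlation). The largest decrease was that of the IGLL1 probe (-4.24, SE 0.37), a surrogate light chain gene whose sequence resembles the immunoglobulin lambda constant genes, and IGJ (now JCHAIN), the joining chain of secreted antibodies, changed by -2.95. Of the 26 genes of memory and cytotoxic T cells 5 fell (14 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 7.20e-10, and adjusted p = 0.114 with an estimated correlation). The lists of NK cell and CD8 T cell genes were called as lower by camera too, though few of their genes passed. NK cell genes fell in 2 of 20 cases (5 adjusted over the list alone; median -0.47) (camera adjusted p = 1.30e-04, and adjusted p = 0.303 with an estimated correlation), and genes of CD8 T cells in 1 of 8 (4 adjusted over the list alone; median -0.61) (camera adjusted p = 0.00892, and adjusted p = 0.262 with an estimated correlation). The mean of the NK cell list reached 6.61 in the negatively selected arrays, averaging 5.80 ± 0.47, and at most 5.45 in the FACS arrays, averaging 5.29 ± 0.14. Much of this came from CD4 negative replicate 3: without it the NK cell list had a median of -0.30 and the CD8 T cell list of -0.44, and the latter was no longer called. Neither CD3D nor CD4, genes by which the cells were defined, passed. CD3D, a chain of the T cell receptor complex, averaged 11.85 ± 0.22 and 11.91 ± 0.09 (adjusted p = 0.954, limma), and CD4 averaged 7.42 ± 0.35 and 7.58 ± 0.20 (adjusted p = 0.84). In all, 99 genes were lower and 4 higher after FACS, 58 of them by at least 2-fold, and 193 differed with the donor as a block. The count was 56, 59, 66 and 68 without CD4 negative replicate 3, FACS replicate 1, FACS replicate 4 and FACS replicate 3, and 60 with arrays centred on their medians, which moved the median gene from -0.04 to 0.06.

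FACS was next compared with positive selection in CD4 cells. Monocyte genes were far lower after FACS, and with them cytokine genes and targets of NF-kappaB that activated monocytes express. Genes of T cells, among them those of naive T cells, were higher. CD14, the monocyte co-receptor for lipopolysaccharide, averaged 8.97 ± 0.48 (n = 5) after FACS and 12.23 ± 0.33 (n = 5) after positive selection, a change of -3.26 (SE 0.23). CST3, a secreted protease inhibitor, and CSF3R, a cytokine receptor of myeloid cells, changed by -3.48 and -3.69. Of the 27 monocyte genes 25 fell, also when adjusted over the list alone (25), with a median of -3.14 (camera adjusted p = 3.83e-15, and adjusted p = 0.17 with an estimated correlation). Genes of monocyte activation moved with them, 23 of 26 falling (24 adjusted over the list alone) with a median of -2.49 (camera adjusted p = 3.61e-11, and adjusted p = 0.113 with an estimated correlation). These included the cytokine genes IL8 (now CXCL8; -3.65), CCL3 (-3.57) and IL1B (-3.11). Among targets of NF-kappaB, a transcription factor of inflammation, 12 of 18 fell (13 adjusted over the list alone; median -1.59) (camera adjusted p = 2.15e-04, and adjusted p = 0.171 with an estimated correlation). Of the immediate early genes, which respond within minutes to stimuli, 14 of 21 fell (14 adjusted over the list alone; median -0.87), with KLF4 at -3.22, IER3 at -3.28 and EGR1 at -1.71 (camera adjusted p = 0.00602, and adjusted p = 0.266 with an estimated correlation). CD69, an early activation marker of lymphocytes, went the other way and was 0.82 (SE 0.16) higher after FACS. T cell genes were higher after FACS in 16 of 17 cases (17 adjusted over the list alone; median 0.65), with CD27 at 1.03 and CD28 at 0.85 (camera adjusted p = 1.09e-06, and adjusted p = 0.158 with an estimated correlation). Genes of naive T cells rose in 15 of 17 cases (15 adjusted over the list alone; median 0.76), with TCF7 at 1.07 and CCR7, a lymph node homing receptor, at 0.92 (camera adjusted p = 8.84e-07, and adjusted p = 0.171 with an estimated correlation). CD4, which monocytes also express, averaged 7.42 ± 0.35 and 7.52 ± 0.25 (adjusted p = 0.703, limma). Altogether 2119 genes differed (774 higher and 1345 lower), 733 by at least 2-fold. Scaling set the split: 1539 genes were higher and 947 lower with quantile normalization, and 1526 and 961 with centred arrays, which moved the median gene from -0.04 to 0.27 and 0.23.

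Positive was then compared with negative selection in CD4 cells, and the monocyte genes again marked the positively selected samples. Inflammatory genes such as IL1B and PTGS2 rose along with CD14, and the T cell receptor chain CD3E and the co-stimulatory receptor CD27 fell. Platelet genes were lower after positive selection. CD14 averaged 12.23 ± 0.33 after positive and 8.86 ± 0.29 after negative selection (n = 5 each), a change of 3.37 (SE 0.23). SERPINA1, C5AR1 and CSF1R, the receptor of a monocyte growth factor, rose by 3.72, 3.53 and 3.37. In the monocyte list 25 of 27 genes rose (27 adjusted over the list alone), with a median of 3.14 (camera adjusted p = 4.51e-20, and adjusted p = 0.141 with an estimated correlation). Monocyte activation genes rose in 21 of 26 cases (21 adjusted over the list alone; median 1.99), with IL8 at 3.16, IL1B at 2.93 and PTGS2, the inducible cyclooxygenase, at 2.76 (camera adjusted p = 2.54e-12, and adjusted p = 0.113 with an estimated correlation). NF-kappaB targets rose in 12 of 18 cases and fell in 1 (12 and 2 adjusted over the list alone; median 1.18) (camera adjusted p = 1.23e-04, and adjusted p = 0.16 with an estimated correlation). T cell genes fell in 14 of 17 cases (16 adjusted over the list alone; median -0.54), with CD27 at -0.78 and CD3E at -0.64 (camera adjusted p = 2.77e-06, and adjusted p = 0.16 with an estimated correlation). Naive T cell genes fell in 9 of 17 cases (13 adjusted over the list alone, median -0.57) (camera adjusted p = 2.39e-04, and adjusted p = 0.266 with an estimated correlation). A mixture of negatively selected CD4 cells with 33.0% monocyte RNA, weighed below, alone gave medians of -0.55 for the T cell list and -0.48 for the naive T cell list. The observed medians, from group means on the linear scale, were -0.53 and -0.55. These falls thus do not by themselves show a change in the T cells. The mixture was not computed for FACS over positive selection. Platelet genes were lower after positive selection in 6 of 20 cases (6 adjusted over the list alone; median -0.47), with SDPR at -1.74 and TUBB1 at -1.66 (camera adjusted p = 5.25e-04, and adjusted p = 0.397 with an estimated correlation), and IGLL1 changed by -3.31. With limma 1494 genes differed (1059 higher and 435 lower), 577 by at least 2-fold. The majority turned to lower genes with quantile normalization (851 higher and 1253 lower) and with centred arrays (875 and 1140), which moved the median gene from -0.07 to -0.28 and -0.23.

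In CD8 T cells, FACS over negative selection showed higher transcripts of genes that natural killer (NK) cells express. Whether these came from NK cells or from cytotoxic T cells was not tested. Platelet genes, IGJ and the IGLL1 probe were lower, as in CD4 cells. SH2D1B, an adaptor protein of NK cells, averaged 7.28 ± 0.70 after FACS (n = 5) and 4.73 ± 0.11 after negative selection (n = 4), a change of 2.55 (SE 0.28). KLRF1, an NK cell receptor, CX3CR1, CD160 and PRF1, which encodes perforin, rose by 2.32, 2.17, 2.03 and 1.71. NK cell genes rose in 11 of 20 cases (18 adjusted over the list alone; median 1.71) (camera adjusted p = 3.70e-21, and adjusted p = 0.114 with an estimated correlation). Monocyte genes lay higher as well: 1 of 27 rose over all genes and 19 when adjusted over the list alone, with a median of 1.39 (camera adjusted p = 1.63e-11, and adjusted p = 0.262 with an estimated correlation). Of these, LYZ averaged 11.89 ± 0.52 and 10.13 ± 1.43 (adjusted p = 0.138, limma) and CD14 averaged 10.12 ± 0.70 and 8.44 ± 1.27 (adjusted p = 0.141); each passed without CD8 negative replicate 4, with changes of 1.27 to 2.39 and 1.41 to 2.30 over the arrays left out. Platelet genes fell in 5 of 20 cases (14 adjusted over the list alone; median -0.77), with GNG11 at -2.20, SEPTIN5 at -2.11 and SDPR at -2.03 (camera adjusted p = 1.65e-14, and adjusted p = 0.114 with an estimated correlation). The histone gene HIST1H2AC changed by -1.53, IGLL1 by -4.21 and IGJ by -3.04. CD8A, a chain of the CD8 co-receptor, averaged 11.91 ± 0.27 and 11.89 ± 0.07 (adjusted p = 0.981, limma). The total was 92 genes (53 higher and 39 lower after FACS), 69 by at least 2-fold, and 184 with the donor as a block. Without FACS replicate 2, negative replicate 5, negative replicate 3 or FACS replicate 5 of the CD8 arrays it was 36, 41, 46 and 56, and a fit of all cell types called 202 genes.

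Against positive selection, FACS-sorted CD8 cells showed lower B cell genes. LMNA, NF-kappaB subunits and enzymes of sterol synthesis were lower as well, and the naive T cell genes MAL and LEF1 were higher. CD79A, a chain of the B cell receptor, averaged 7.56 ± 0.34 after FACS and 9.91 ± 0.68 after positive selection (n = 5 each), a change of -2.36 (SE 0.31), and MS4A1, which encodes CD20, changed by -1.10. B cell genes fell in 13 of 20 cases (17 adjusted over the list alone; median -1.01) (camera adjusted p = 3.17e-12, and adjusted p = 0.157 with an estimated correlation). IGLL1 (-4.81) and IGJ (-3.51) had the largest decreases of the named genes. LMNA, which encodes lamins A and C of the nuclear envelope, averaged 7.11 ± 0.51 and 10.11 ± 0.21, a change of -3.00 (SE 0.24), and ELL2, an elongation factor of RNA polymerase II, changed by -2.59. NF-kappaB targets fell in 7 of 18 cases (8 adjusted over the list alone; median -0.48) (camera adjusted p = 0.00176, and adjusted p = 0.318 with an estimated correlation). The pathway subunits RELB (-1.58) and REL (-1.23), the maturation marker CD83 (-1.69) and IL6 (-2.03) were also lower after FACS. Genes of sterol synthesis fell in 3 of 12 cases (5 adjusted over the list alone; median -0.55), namely HMGCS1 (-1.18), SQLE (-1.16) and INSIG1 (-0.99) (camera adjusted p = 0.00179, and adjusted p = 0.183 with an estimated correlation). Naive T cell genes rose in 6 of 17 cases (10 adjusted over the list alone; median 0.50), with MAL at 1.05 and LEF1 at 0.72 (camera adjusted p = 3.01e-06, and adjusted p = 0.16 with an estimated correlation). ARHGEF3, GIMAP8 and CD69 were higher after FACS by 1.19, 1.39 and 0.75. CD8A averaged 11.91 ± 0.27 and 11.89 ± 0.30 (adjusted p = 0.972, limma). There were 514 genes (151 higher and 363 lower), 161 of them 2-fold or more apart, and the split was 212 higher and 319 lower with centred arrays.

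Positive over negative selection in CD8 cells moved NK and B cell genes together. Both groups were higher after positive selection, while naive T cell genes were lower. The source of the NK cell genes was not tested here either. GZMB, the cytotoxic protease granzyme B, averaged 11.28 ± 0.51 after positive (n = 5) and 8.85 ± 1.13 after negative selection (n = 4), a change of 2.43 (SE 0.44). SH2D1B, KLRF1 and NCAM1, which encodes the NK cell antigen CD56, rose by 2.32, 2.06 and 1.67, and NK cell genes rose in 14 of 20 cases (18 adjusted over the list alone; median 1.68) (camera adjusted p = 7.27e-15, and adjusted p = 0.158 with an estimated correlation). B cell genes rose in 10 of 20 cases (18 adjusted over the list alone; median 1.05), with CD79A at 1.92 and VPREB3 at 1.96 (camera adjusted p = 1.21e-11, and adjusted p = 0.158 with an estimated correlation). Naive T cell genes fell in 8 of 17 cases (10 adjusted over the list alone; median -0.69), with ACTN1 at -1.14 and LEF1 at -0.97 (camera adjusted p = 3.84e-09, and adjusted p = 0.114 with an estimated correlation). RELB, CD83 and IL6 rose by 1.25, 1.26 and 1.89. The transcription factor genes NFE2 and MYB changed by -1.54 and -1.47. CD8A averaged 11.89 ± 0.30 and 11.89 ± 0.07 (adjusted p = 0.989, limma). The 388 genes that differed (274 higher and 114 lower), 160 of them by at least 2-fold, became 706 with the donor as a block and 177, 184 and 204 without CD8 negative replicate 5, negative replicate 3 and positive replicate 2. With quantile normalization 206 were higher and 165 lower, and with centred arrays, which moved the median gene from 0.04 to -0.07, 188 and 201.

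**Figure D2:**
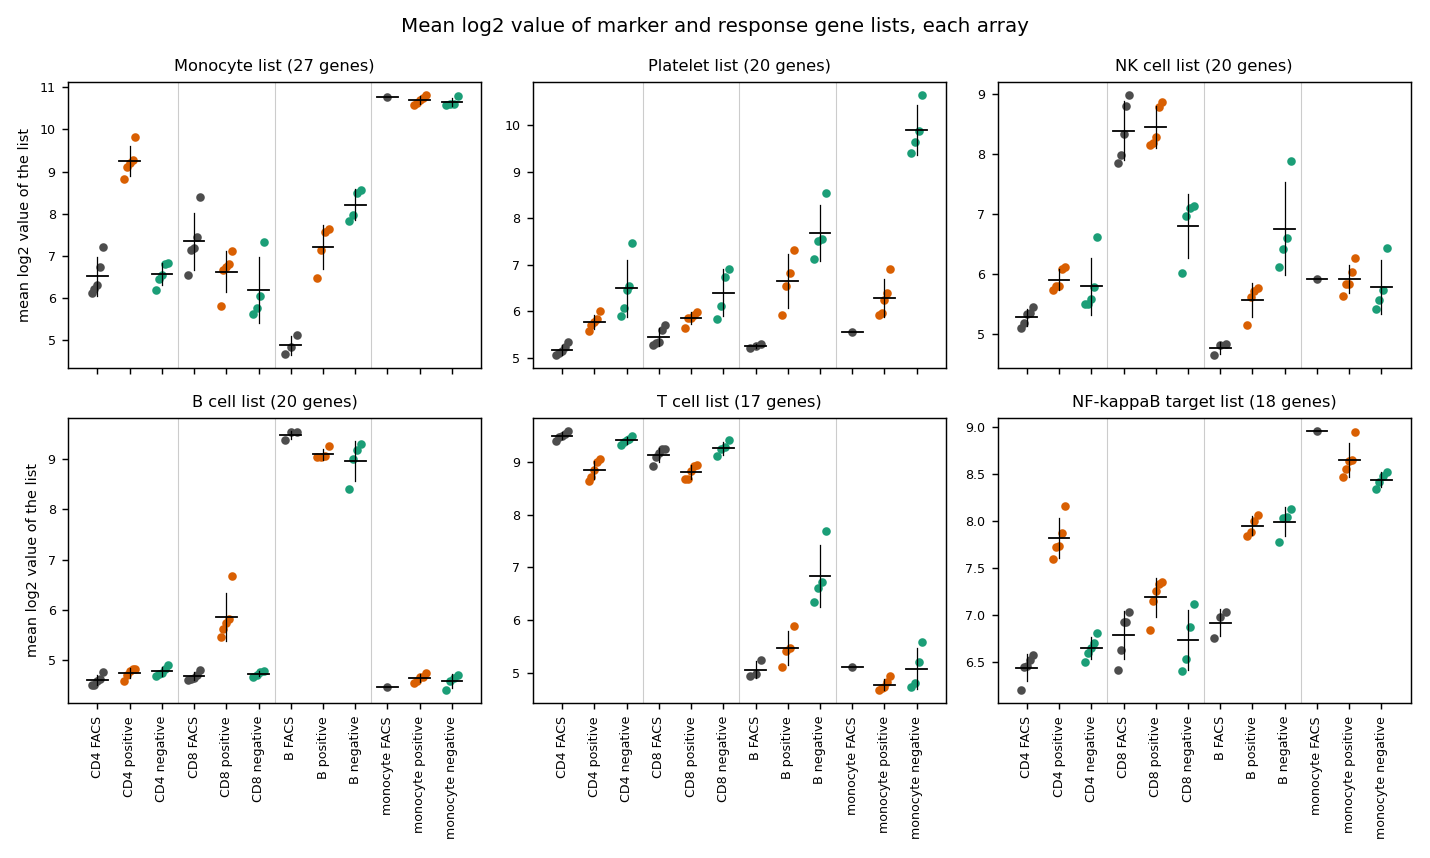
Mean log2 value of the genes of 6 lists on each array (vertical axes), by cell type and isolation method; points are arrays, horizontal bars group means and vertical lines 1 SD, with a single array for FACS monocytes. The monocyte list is highest in monocytes, and among CD4 groups in the positively selected one, where its median change over negative selection was 3.14. The platelet list is highest in negatively selected monocytes, and its median change in positive over negative selection of monocytes was -3.81.

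In B cells, FACS was compared with negative selection, and genes of monocytes, platelets, T cells and NK cells were lower after FACS. Plasma cell genes such as IGJ were higher, and the B cell gene CD79A did not pass. LYZ, the lysozyme of monocytes and granulocytes, averaged 6.40 ± 1.01 after FACS (n = 3) and 12.49 ± 0.34 after negative selection (n = 4), a change of -6.09 (SE 0.52). IL8, IL1B, S100A9 and CD14 changed by -6.69, -6.59, -6.38 and -5.94. Monocyte genes fell in 22 of 27 cases (24 adjusted over the list alone; median -3.88) (camera adjusted p = 7.88e-25, and adjusted p = 0.139 with an estimated correlation). Platelet genes fell in 13 of 20 cases (15 adjusted over the list alone; median -2.39), with TUBB1 at -5.14 and PPBP at -4.80 (camera adjusted p = 2.36e-11, and adjusted p = 0.247 with an estimated correlation). T cell genes fell in 11 of 17 cases (14 adjusted over the list alone; median -1.72), with CD3D at -3.21 and BCL11B at -2.89 (camera adjusted p = 1.15e-08, and adjusted p = 0.256 with an estimated correlation). NK cell genes fell in 11 of 20 cases (13 adjusted over the list alone; median -1.44), with GZMB at -4.11 and GNLY, the cytolytic protein granulysin, at -4.06 (camera adjusted p = 4.65e-08, and adjusted p = 0.262 with an estimated correlation). Plasma cell genes rose in 4 of 9 cases (5 adjusted over the list alone; median 0.68), led by IGJ (2.54) and TXNDC5, a disulfide isomerase of the secretory pathway (1.31) (camera adjusted p = 0.00113, and adjusted p = 0.202 with an estimated correlation). CD79A averaged 13.11 ± 0.21 and 12.64 ± 0.27 (adjusted p = 0.209, limma). The mean of the B cell list was higher on every FACS array (9.39 to 9.53) than on the negatively selected (8.40 to 9.29) and positively selected ones (9.04 to 9.27). The comparison gave 584 genes, 55 higher and 529 lower after FACS, 485 of them at least 2-fold apart. The split was 187 and 397 with quantile normalization and 219 and 384 with centred arrays, which moved the median gene from -0.05 to 0.18 and 0.21.

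Positively selected B cells also carried more monocyte transcripts than FACS-sorted ones. Platelet genes and NF-kappaB targets were higher with them, and TXNIP was lower. LYZ averaged 6.40 ± 1.01 after FACS (n = 3) and 11.35 ± 1.03 after positive selection (n = 4). The changes that follow are those of FACS over positive selection. IL8, S100A9 and PLAUR, the urokinase receptor, changed by -5.94, -5.10 and -4.12 (SE 0.42, 0.47 and 0.33). Monocyte genes fell in 19 of 27 cases (21 adjusted over the list alone; median -2.42) (camera adjusted p = 9.40e-21, and adjusted p = 0.157 with an estimated correlation). Platelet genes fell in 8 of 20 cases (10 adjusted over the list alone; median -1.19), with TUBB1 at -3.47 and PPBP at -3.41 (camera adjusted p = 1.26e-06, and adjusted p = 0.336 with an estimated correlation). NF-kappaB targets fell in 7 of 18 cases (8 adjusted over the list alone; median -0.63) (camera adjusted p = 1.42e-06, and adjusted p = 0.113 with an estimated correlation). TXNIP, an inhibitor of thioredoxin, averaged 12.85 ± 0.31 and 11.18 ± 0.36 and was 1.67 (SE 0.25) higher after FACS. TCL1A, a marker of naive B cells, was 1.75 higher, a call lost without B FACS replicate 1, with changes of 1.48 to 1.90 over the arrays left out. The T cell gene CD3D averaged 5.82 ± 0.40 and 6.67 ± 0.89 (adjusted p = 0.321, limma). In total 317 genes differed (58 higher and 259 lower), 261 by at least 2-fold, against 127 with the donor as a block and 175, 198 and 204 without B FACS replicate 1, FACS replicate 2 and positive replicate 4. Quantile normalization gave 100 higher and 202 lower genes, and centred arrays, which moved the median gene from -0.06 to 0.13, gave 142 and 184.

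Between positive and negative selection of B cells, transcripts of T and NK cells were lower after positive selection. Plasma cell genes were higher. CD3D averaged 6.67 ± 0.89 after positive and 9.03 ± 0.70 after negative selection (n = 4 each), a change of -2.37 (SE 0.42). T cell genes fell in 9 of 17 cases (14 adjusted over the list alone; median -1.55), with BCL11B at -2.40 and CD247, the zeta chain of the T cell receptor, at -2.39 (camera adjusted p = 4.07e-10, and adjusted p = 0.22 with an estimated correlation). NK cell genes fell in 4 of 20 cases (12 adjusted over the list alone; median -1.36), with NKG7 at -2.58 (camera adjusted p = 2.71e-07, and adjusted p = 0.266 with an estimated correlation). Monocyte genes fell in 5 of 27 cases and in 21 when adjusted over the list alone (median -1.16) (camera adjusted p = 7.20e-10, and adjusted p = 0.266 with an estimated correlation), and IL1B changed by -1.77. Plasma cell genes rose in 4 of 9 cases (5 adjusted over the list alone; median 0.69), with IGJ at 2.51 and ELL2 at 1.94 (camera adjusted p = 5.70e-06, and adjusted p = 0.139 with an estimated correlation). RBBP8, a DNA repair endonuclease partner, and CNOT6L, a deadenylase subunit, rose by 1.86 and 1.56. Here 183 genes differed by limma (59 higher and 124 lower), 154 by at least 2-fold, and 105 higher and 118 lower with quantile normalization. Single arrays decided the count, which was 55, 66, 100, 101 and 108 without B positive replicate 2, negative replicate 3, negative replicate 5, positive replicate 3 and positive replicate 5, and 297 without negative replicate 4.

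In monocytes, the platelet list had the largest median change of all lists tested between positive and negative selection. Histone and red cell genes were lower after positive selection too, and FCER1A, CD1C and CLEC10A, which conventional dendritic cells express, were higher. The monocyte marker CD14 did not pass. TUBB1 averaged 7.61 ± 0.68 after positive (n = 5) and 12.57 ± 0.38 after negative selection (n = 4), a change of -4.96 (SE 0.33). GNG11, SDPR, GP9, a subunit of the platelet receptor for von Willebrand factor, and PPBP changed by -5.09, -4.81, -4.80 and -4.55. Platelet genes fell in 19 of 20 cases (20 adjusted over the list alone; median -3.81) (camera adjusted p = 1.48e-44, and adjusted p = 0.114 with an estimated correlation). Histone genes fell in 9 of 9 cases, also when adjusted over the list alone (median -2.87), with HIST1H2AC (now H2AC6) at -4.72 and HIST1H3H (now H3C10) at -4.53 (camera adjusted p = 6.23e-19, and adjusted p = 0.114 with an estimated correlation). Red cell genes fell in 3 of 5 cases (4 adjusted over the list alone; median -2.02), with the alpha globin gene HBA2 at -2.83 (camera adjusted p = 4.94e-05, and adjusted p = 0.158 with an estimated correlation). Genes of conventional dendritic cells rose in 6 of 13 cases (9 adjusted over the list alone; median 0.73) (camera adjusted p = 5.98e-08, and adjusted p = 0.114 with an estimated correlation). FCER1A, a chain of the high-affinity IgE receptor, averaged 10.54 ± 0.79 and 7.50 ± 1.22, a change of 3.05 (SE 0.54), and CD1C, a lipid antigen-presenting molecule, and CLEC10A, a lectin, rose by 1.58 and 1.32. CD14 averaged 13.71 ± 0.12 and 13.90 ± 0.06 (adjusted p = 0.622, limma). The 221 genes that differed comprised 22 higher and 199 lower ones, 187 of them at least 2-fold apart.

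The single FACS monocyte array had no replicate, so its differences are descriptive and carry no test, and since it comes from 1 donor and the groups from up to 5, method and donor are not separated. Against the mean of the 5 positively selected monocyte arrays 93 genes lay at least 2-fold higher and 303 at least 2-fold lower while outside the range of those arrays, and against the 4 negatively selected arrays 133 and 415. Cytokine and chemokine genes lay a median of 0.91 above positive selection and 1.15 above negative selection, each at percentile 100 of 10000 random gene lists of the same size and expression. Monocyte activation genes lay 0.83 and 0.90 above, also at percentile 100. These percentiles compare genes within 1 array and do not measure the spread between arrays. Genes of a list can also vary together, which random lists leave out. The cytokine list averaged 9.07 on the FACS array and 7.66 to 8.65 on the positively selected arrays. For the monocyte activation list these values were 10.03 and 9.13 to 9.78. Lists of other cells moved on the same array too: against positive selection CD8 T cell genes lay 0.68 above (percentile 99.99), neutrophil genes 0.43 (99.98) and T cell genes 0.35 (99.68), and the 4 measured ribosomal protein genes at -1.25 (0.12), and against negative selection at 0.43 (99.16), 0.00 (55.55), -0.10 (49.8) and -1.01 (1.54). Against the single positively selected array of the same donor the cytokine genes lay a median of only 0.41 above and the monocyte activation genes 0.20, and the platelet and conventional dendritic cell genes at -0.39 and -0.76, while the CD8 T cell, neutrophil and T cell genes lay 0.57, 0.31 and 0.32 above and the ribosomal protein genes at -0.73. Platelet genes lay at -0.76 and -4.23 and histone genes at -0.16 and -2.87, and genes of conventional dendritic cells at -0.83 against positive selection (percentile 0.01) and 0.07 against negative selection (percentile 54.8).

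The series asked how the way cells are isolated affects their expression over a short time. Genes of the heat shock response, which refolds damaged proteins, of endoplasmic reticulum stress, of p53 and of the interferon response were not called as lists. In none of the 10 comparisons did camera call the lists of heat shock, endoplasmic reticulum stress, p53 and apoptosis, or interferon-stimulated genes, with smallest adjusted p of 0.144, 0.218, 0.208 and 0.158, and for each of them the count at an unadjusted p under 0.05 was 0 of 10 as well. Only 9 of 23, 3 of 18, 12 of 25 and 16 of 38 genes of these lists were measured, so that of endoplasmic reticulum stress rests on 3 genes, with medians from -0.74 to 0.68. Single members passed, mostly in CD4 cells: in FACS over positive selection 4 of 9 heat shock genes rose and 2 fell (4 and 2 adjusted over the list alone), and 6 of 12 p53 and apoptosis genes fell and 1 rose (6 and 1 adjusted over the list alone). HSPA1A, an inducible chaperone, averaged 4.89 ± 0.49 after FACS and 6.34 ± 0.96 after positive selection of CD4 cells, a change of -1.45 (SE 0.38, limma adjusted p = 0.00498), and 7.59 in positively selected monocytes. It did not pass in the other 9 comparisons. HSPA8, a constitutive chaperone, averaged 11.43 ± 0.06 after FACS and 11.57 ± 0.04 after negative selection of CD4 cells (limma adjusted p = 0.76). The immediate early list was called in 4 comparisons, with medians between -0.87 and 0.50 over the 10, and the NF-kappaB list in 6, with medians between -1.59 and 1.18. By camera with an estimated correlation their smallest adjusted p was 0.262 and 0.113. In positive over negative CD4 cells the mixture with monocyte RNA alone gave medians of 0.68 for the immediate early list and 1.10 for the NF-kappaB list. The observed medians, from group means on the linear scale, were 0.52 and 1.15. Those changes thus need no response of the T cells. Over all lists camera called 127 of 330 tests with its preset correlation of 0.01 and 0 with an estimated correlation, where 66 had an unadjusted p under 0.05.

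Whether a method difference depended on the cell type was tested with a moderated F statistic in a fit of all cell types. The effect of positive over negative selection differed between the 4 cell types for 1527 of 4717 genes, and that of FACS over negative selection between CD4, CD8 and B cells for 740. SLC2A6, a glucose transporter family member, changed by 2.48 in CD4 cells but by -0.01, -0.15 and 0.33 in CD8 cells, B cells and monocytes (positive over negative; F 53.1, limma adjusted p = 3.98e-11). CEBPD, a transcription factor of myeloid cells, changed by 2.95, 1.31, -1.51 and -0.04 in the same order (F 51.9). ANXA1, an anti-inflammatory phospholipid-binding protein, changed by -0.16, 0.04 and -5.06 in CD4, CD8 and B cells in FACS over negative selection (F 125). TYROBP and FCER1G, adaptors of myeloid and NK cell receptors, changed by 1.83 and 1.86 in CD8 cells and by -5.27 and -5.56 in B cells. On simulated data with the spreads of these cell types 14.9% and 14.3% of the calls were false, against 4.13% and 5.08% with a single spread, so the F counts hold more false calls than their threshold implies. Among the 15 CD4 arrays, a median over the 4717 genes of 38.1% of a gene's variance lay between methods, 21.7% between donors and 28.0% in neither. These terms had 2, 4 and 8 degrees of freedom and the shares are not corrected for them. The donor share alone thus does not measure a donor effect. All 3 shares hold only for genes that the authors' filter kept. Of the listed genes it kept 4 of 42 for ribosomal proteins and 0 of 51 for respiratory chain subunits. The method share includes the monocyte genes that rose after positive selection.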

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

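Of the tests weighed here, those of the monocyte genes in CD4 cells and those of a lower share of monocytes and of scaling for the platelet genes were chosen after the result was seen. The test of platelet RNA was set after the pattern but before its own value was seen, and the splits of the samples were planned before.

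An array far from the others of its group was looked for with Dixon's ratio, the gap to the nearest array over the range of the group. Of 601 groups tested 33 passed the 95% critical value, where chance flags about 1 in 20 groups and 30.05 were expected, so most single results need no explanation. Among list means these were the B cell list in positively selected B cells (0.923), the NK cell list in negatively selected CD4 (0.750) and CD8 cells (0.860), and the conventional dendritic cell list in negatively selected CD8 cells (0.831). The others were the monocyte list in negatively selected monocytes (0.878), and the monocyte activation (0.741) and cytokine lists (0.713) in positively selected monocytes. The array median passed in negatively selected CD8 cells (0.916).

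Single genes passed as follows. In negatively selected B cells BCL11B had a ratio of 0.915, IL7R of 0.927 and PTGS2 of 0.893. In positively selected B cells BCL11B had 0.831, ELL2 0.956, IGJ 0.930, IL1B 0.845, NUPL1 0.849 and TCL1A 0.958. In FACS CD4 cells BACH2 had 0.762, CD4 0.824, EGR1 0.885 and IGJ 0.745, and in negatively selected CD4 cells LILRA2 had 0.925. In positively selected CD4 cells CD300LF had 0.811, EGR1 0.731 and OLR1 0.794. CD14 had 0.830 in negatively selected CD8 cells. In positively selected CD8 cells CD79A had 0.739, HBEGF 0.750, HMGCS1 0.793, IGJ 0.767 and RELB 0.723. CLEC10A had 0.891 and TUBB1 0.941 in negatively selected monocytes.

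Method effects that differed between cell types, by the moderated F test, covered 1527 genes for positive over negative selection and 740 for FACS over negative selection. Random method labels within each cell type, drawn without regard to the donor, gave at most 805 and 559 genes, and the real labels were the only 1 of 100 groupings to give as many in either case. The largest F for positive over negative selection were those of SLC2A6 (53.1), CEBPD (51.9), RXRA (49.4), IER3 (49.2), OSCAR (47.4) and PLXNB2 (46.6), higher in CD4 cells after positive selection, and of TMEM140 (48.9) and CCL5 (45.6), lower in monocytes. For FACS over negative selection they were those of ANXA1 (125), CEBPD (107), TYROBP (104), FCER1G (94.6), TIMP1 (86.3), AIF1 (85.7), IER3 (85.1) and HBEGF (83.6), each lower in B cells after FACS.

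Monocyte genes were higher in positively selected CD4 cells. A shift of whole arrays left in the deposited values was argued against by a median change of the monocyte list of at least 2.98 with quantile normalization or centred arrays. Array medians of the groups differed by only 0.15 log2, so centring could hardly have moved the list. The authors' own scaling could not be undone, so its effect was not tested. Monocyte RNA in the samples is a candidate explanation: of 22 usable genes of the list 100% needed a share within 2 times the median share, 33.0%. The abundant S100A9, S100A8, FCN1, CD14 and CST3 among them needed 47.2%, 37.7%, 42.4%, 34.1% and 31.9%. LYZ, not among the usable genes because its level in negatively selected CD4 cells was too high, needed 45.1%. Across genes, which are not independent replicates, observed and mixture changes correlated at r = 0.959, and 553 of 553 genes at least 2-fold higher lay within 1 log2 of the mixture. A response of the T cells as the source of the monocyte genes was argued against by these shares. They had quartiles of 28.5% and 37.5%, so the genes rose nearly in proportion to their level in monocytes. Of 1059 higher genes 0 lay 1 log2 or more above the mixture. Only 553 of them rose by at least 2-fold, so many others could hardly have exceeded it by that much. The share was also fitted to these same arrays. A T cell response under 2-fold would thus pass unseen in this count and in that of the 553 genes. Whether the T cells responded to positive selection in other genes stays open. The T cell activation list lay at a median of -0.0765 log2 relative to a mixture of negatively selected CD4 cells with monocyte RNA. Its genes went both ways (quartiles -0.26 and 0.18), which decides nothing. Monocytes carry CD4, so selection by CD4 alone would not remove them, and whether the isolation steps included another depletion of monocytes was not examined here.

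Platelet genes were higher in negatively selected monocytes. A lower share of monocytes was argued against by the lists of T, NK and B cells, the nearest of which lay 3.39 log2 from the platelet list. A shift of whole arrays left in the deposited values was argued against by a change of the platelet list that stayed at 3.56 log2 or more in size with other scalings. The shift of array medians was only -0.02, so centring could hardly have moved the list. The authors' own scaling could not be undone. Platelet RNA in the negatively selected samples is a candidate explanation: across 19 genes, not independent replicates, the excess in negatively selected monocytes and that in negatively selected B cells correlated at r = 0.967. The correlation was 0.943 with CD4 cells and 0.908 with CD8 cells. No biological explanation was tested for this pattern. A change in the platelets themselves was not tested either, and it would also need platelet RNA in these samples.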

How the results depend on the processing

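The alternatives of quantile normalization, centred arrays and leaving out genes of mean log2 under 5 were chosen after seeing the data. Not run were the normalizations and detection filters of scanner values and the slide as a block, since scanner columns match no sample, and the random donor block for lists; the deposited values and no detection filter were the main setting. The filtered table holds no detection values, so how signal over background limits a call is unknown. For the changes below the cause was not tested unless named.

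For FACS over negative selection in CD4 cells the count was 60 with centred arrays, 193 with the donor as a block, 160 with it as a random block, 66 with only the 2 groups in the fit and 58 with a log2 change of at least 1 required. That requirement, stricter by construction, gave 733 for FACS over positive and 577 for positive over negative selection in CD4 cells, and 161 and 160 in CD8 cells. With the donor block CD8 FACS over negative gave 184 (random block 181) and positive over negative 706 (664), and B FACS over positive gave 127; B positive over negative gave 395 with the random block. All cell types in 1 fit gave 202 for CD8 FACS over negative, 662 for B FACS over positive and 677 for B positive over negative. Only the 2 groups gave 49 for CD8 FACS over negative and 93 for B positive over negative, where eBayes with trend and robust gave 278. With an estimated correlation 0 of 127 list calls held.

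Leaving out 1 array at a time gave 56 to 112 genes for CD4 FACS over negative, 36 to 124 for CD8 FACS over negative, 177 to 377 for CD8 positive over negative, 175 to 276 for B FACS over positive and 55 to 297 for B positive over negative, and stayed within 1.5 times the count elsewhere.

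Reversed directions were those of genes that had not passed. CD3D, CD4 FACS over negative, was 0.0600 with quantile normalization and 0.0462 with centred arrays, and -0.14 to 0.00459 over the arrays left out. CD4, CD4 FACS over positive, was 0.0498 and 0.17, and -0.18 to 0.0626. CD8A was -0.0342 and -0.0342 for FACS over negative, and -0.0684 to 0.11; -0.18 and -0.10 for positive over negative, and -0.0609 to 0.12; and -0.10 to 0.11 for FACS over positive. MS4A1 ran from -0.0924 to 0.74 for B FACS over negative.

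Of 277 values of named genes 267 kept their direction and call with the donor block, 266 with quantile normalization, 265 with centred arrays, 264 with all cell types in 1 fit and 259 with only the 2 groups. The block lost FCER1G in CD8 FACS over negative, NUCKS1 and CD38 in B FACS over negative, TADA1L, BTLA, ZNF101, REL, CD69 and EGR1 in B FACS over positive (there also RELB, PMEPA1 and TUFT1, named among the 17 shared genes below), and gained CD14 in B positive over negative. Of 127 called lists 121 kept their call with the block, 126 with quantile normalization, 123 with centred arrays, 122 with all cell types in 1 fit, 112 with fry and 114 without genes of mean log2 under 5. The block lost metallothioneins and cytoskeleton genes in CD4 FACS over negative, and, in B cells, hypoxia genes for FACS over both other methods and sterol synthesis and metallothionein genes for FACS over positive.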

Other observations

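Among the tests below, those of monocyte RNA and of scaling for LMNA and 16 other genes were chosen after the result was seen, as were the naming of the shared genes, the counts of overlap between cell types and the counts of shared genes that passed with the donor as a block.

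Positive selection shared a set of higher genes in CD8 T cells and B cells. LMNA and 16 other genes were higher in positively selected cells than with either other method in both cell types. In CD8 and B cells 152 and 24 genes met this, and 0.77 would be shared by chance if calls in the cell types were independent. The 17 shared genes include the NF-kappaB subunits REL and RELB, MIR155HG, the host transcript of a microRNA induced on lymphocyte activation, IL21R, ELL2, RBBP8, PMEPA1, TUFT1 and CASP9. With the donor as a block 6 of the 17 genes still passed in all 4 comparisons (LMNA, ELL2, RBBP8, CASP9, IL21R and MIR155HG), and the other 11, REL and RELB among them, lost their call in positive selection against FACS in B cells. Only 2 donors had both kinds of these B cell arrays. On simulated data without a donor effect the block recovered 10% of changes of 1 log2 there, against 44% without it. A call lost there with the block thus does not show that the change depended on the donor. REL also lost its call in positive over negative CD8 cells in 7 of the 9 fits that left out 1 array. The set was not rerun with arrays left out. The count of B positive over negative selection, which enters it, ran from 55 to 297 genes over those fits. LMNA averaged 7.11 after FACS, 8.40 after negative and 10.11 after positive selection in CD8 cells, and 6.79, 8.16 and 9.59 in B cells. B cell RNA in the positively selected CD8 samples, whose share would be 5.93% if it gave the whole change of the B cell list, was argued against as the whole cause. It predicted changes from 0.038 (IL21R, observed 1.18) to 0.84 (PMEPA1, observed 1.63). The observed change exceeded its prediction by a median of 0.87 log2 (quartiles 0.79 and 1.01), for 17 of 17 genes. The genes were chosen for passing in this same comparison, which favours large observed changes. The size of the excess and the count of genes are thus in part set by that choice. Monocyte RNA as the whole cause was argued against by the monocyte list, which changed by a median of -1.16 in positive over negative B cells and was 0.84 higher after FACS than after positive selection in CD8 cells. In positive selection over FACS in B cells the list was 2.42 higher, and in positive over negative CD8 cells 0.56 higher, so a part played by monocyte RNA in these 2 comparisons stays open. Scaling differences left in the deposited values were argued against as the whole cause by quantile normalization, with which at least 92.6% of the median change of the 17 genes was kept in each of the 4 comparisons, and with centred arrays at least 84.1%. The authors' own scaling could not be undone. Array medians differed by at most 0.19 log2 in these comparisons, where the smallest change of the 17 genes was 0.66. The calls depend on scaling in part, since 5 genes with quantile normalization and 8 with centred arrays no longer passed in all 4. In CD4 cells 10 of the 17 genes lay higher after positive than negative selection and 7 lower (median 0.40), of which 6 passed as higher, RBBP8 (1.19) and ELL2 (0.84) among them, and 0 as lower by limma; IL21R (-0.45) and TUFT1 (-0.37) were among the lower ones. LMNA did not pass there (0.40, limma adjusted p = 0.174) or in monocytes (-0.22, limma adjusted p = 0.891). The CD4 values were not corrected for the monocyte genes that rose in that comparison, with a share of 33.0% in the mixture. Centred arrays also moved the median gene of that CD4 comparison to -0.23. A response of lymphocytes to positive selection may explain the genes shared by CD8 and B cells, but it was not tested. Of the genes higher in positive over negative CD8 cells 19 were higher and 14 lower in B cells, where 3.43 higher ones were expected by chance if calls in the cell types were independent.

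A set of 21 genes was lower after positive selection than after FACS in CD4, CD8 and B cells. By chance 0.30 were expected if calls in the cell types were independent. With the donor as a block 4 of the 21 genes (TXNIP, ARHGEF3, ZNF439 and ZNF564) still passed in all 3 cell types, and 17, SLAMF6, CRLF3 and CD69 among them, lost their call in B cells. The block has little power in that B cell comparison, as given above. TXNIP was higher after FACS by 0.51, 1.06 and 1.67 in the 3 cell types, ARHGEF3 by 0.61, 1.19 and 1.19, SLAMF6 by 0.50, 0.76 and 1.24, and CRLF3 by 0.72, 0.92 and 0.97. CD69 was higher by 0.82, 0.75 and 1.13, and the call in B cells was also lost without B FACS replicate 1. In the other direction 59 genes were higher after positive selection in all 3 cell types, with 5.68 expected, and 26 of these still passed with the donor as a block. Against negative selection, 11 genes were lower after positive selection in CD4, CD8 and B cells (0.28 expected), among them MAL, LEF1, PRKCQ and GIMAP6, which T cells express, and all 11 still passed with the donor as a block. In CD4 cells the mixture with monocyte RNA alone gives -0.31 for TXNIP and -0.46 for CD69 in positive over negative selection, and no other technical explanation was tested for these sets.

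Lists of genes of other cells differed between methods in further comparisons. If RNA of monocytes gave the whole change of the monocyte list, its share would be 5.63% in FACS over negatively selected CD8 cells, where 1 of 27 genes passed by limma (19 adjusted over the list alone). In B cells it would be 14.8% after negative and 6.15% after positive selection over FACS, and the share of T cell RNA 15.1% after negative selection. The shares needed by single genes lay within 2 times these medians for 20 of 21, 21 of 22, 19 of 22 and 11 of 12 usable genes. No rival explanation was tested for these lists, so their source stays open. The B cell list would need 5.93% in positively selected CD8 cells, with 17 of 17 usable genes within 2 times this share. In positively selected CD4 cells it gave 0.10% with 0 of 14 within 2 times and quartiles of -0.21% and 0.34%, so this value is not distinct from 0. Lower genes with FACS over negative selection were shared by CD4 and CD8 cells in 23 cases, with 0.82 expected, and 14 genes, TUBB1, PPBP and SDPR among them, were lower in FACS over negative selection of CD4, CD8 and B cells and in positive over negative selection of monocytes. Of the genes lower in positively than negatively selected CD4 cells 21 of 435 lay at least 1 log2 below the mixture with monocyte RNA, and none of the higher genes lay that far above it (0 of 1059). Only 553 of the higher genes rose by at least 2-fold, so this count could not show smaller responses.

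Of the splits of the arrays made without regard to the donor only 1, the real grouping, gave as many genes in each of the 10 comparisons (100 of 126 possible splits for CD4, CD8 and monocyte comparisons, all 35 for B cells). For CD4 cells the highest other split gave 1 gene for FACS over negative selection (real, 99 lower and 4 higher), 764 for FACS over positive selection (2119) and 405 for positive over negative selection (1494). For CD8 cells these were 16 (92), 1 (514) and 11 (388), in the same order. For B cells they were 204 (584), 107 (317) and 3 (183), and for monocytes 38 (221). Arrays of the same donor are alike, so these splits are no full reference, and the splits that part all donor pairs, as the real one does, are too few for a share under 0.05 (16; 12, 12 and 8 for B cells). Among these the highest other was 1, 0 and 0 in CD4 cells, 2, 0 and 0 in CD8 cells, 204, 0 and 0 in B cells and 0 in monocytes. The highest other splits part fewer pairs than the real one in 8 comparisons, and for B FACS over negative selection the highest (204) parts all pairs, the highest that parts fewer giving 170.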
